A study of Mus musculus with 5 samples.

How the data were processed

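RNA was measured by poly-A selected, non-stranded RNA sequencing of cells sorted from the back skin of male mice. Per the labels, 2 libraries came from quiescent melanocyte stem cells (McSC) at postnatal days 60 and 62, in the second resting phase (telogen) of the hair cycle. The other 3 came from melanocytes at postnatal day 10, in full growth phase (anagen). Each library pooled cells from 2 to 4 males and is a biological replicate per the labels.

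The file used holds counts per gene and library, as deposited by the authors; the values are whole numbers, so they were read as raw counts without normalization or pooling of replicates. Per the submitters' processing notes, the genome build mm10, STAR 2.5.2a and Salmon 0.8.2 were used, without a statement of their roles. The program that made the gene counts and the annotation are not given in the sources used here. The table lists 24100 genes by Entrez identifier, and 24045 of these matched a RefSeq symbol of the same build (GRCm38.p6, that is mm10). All printed coordinates are on that build. No mitochondrially encoded gene is in the table, and 3738 genes had no count in any library. Reads of near-identical paralogs could be split in ways that the counts do not show, and reads from overlapping or antisense genes cannot be told apart without strand.

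Total counts ranged from 17512381 to 124530834 per library, a 7.11-fold range. A count of 3 corresponded to between 0.0241 and 0.171 CPM (counts scaled by library size) in the deepest and shallowest library. Where a group had no count of a gene, the fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is given with its exact 95% conditional binomial interval. These bounds and ratios use counts summed over a group and its TMM-scaled library sizes, so they differ from ratios of mean CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

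Genes were filtered with filterByExpr, normalized with TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 5 libraries entered one fit without covariates. Log2 fold changes are melanocyte minus quiescent McSC, and each standard error (SE) was derived from the fold change and the F statistic. CPM values are TMM-normalized and given as mean ± SD (n = 2 quiescent McSC and n = 3 melanocyte libraries). A gene is called when its adjusted p is under the threshold. Counts were simulated for the 16953 tested genes at the real means and library sizes, and 16671 of these passed the filter again. Changed genes were drawn only from those above a floor of mean CPM, so the recovery rates do not cover genes of low counts. The procedure was tested on these simulated counts. It recovered 0% of 1.5-fold, 30% of 2-fold, 72% of 4-fold and 96% of 8-fold changes, with 50 genes per size. It called 10 unchanged genes. The simulation changed a far smaller share of genes than was called in the real data (55.4% of tested genes). Its Benjamini-Hochberg cutoff was therefore stricter, so these rates do not give the power of the real comparison.

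Before the data were examined, 23 gene lists, 8 lists of markers of other skin cell types and a rule for named genes were fixed. The rule took the genes of the sorting markers, the 8 genes with the largest change in each direction among called, non-overlapping genes of at least 20 CPM, up to 3 members of each list with the smallest p, and 8 BMP receptor and target genes. It gave 123 genes. Other list members named in the text, all members plotted by library, and members named to spell out small counts were chosen after their values were seen. Some members of the Schwann cell, neural crest, TGF-beta and cholesterol lists are counted but not reported here by name. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 23 gene lists or the 8 marker lists. Camera compares a list with all other genes. Where the correlation is estimated instead, its degrees of freedom come from the 5 libraries and not from the genes, so that setting has little power here. Counts of called members refer to adjustment over all 16953 tested genes, and those adjusted over the list alone are given beside them. Of the list members, 4 were not in the table and 2 were found by an older symbol.

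Alternatives fixed beforehand were other size factors, library size only, leaving the 20 most abundant genes out of library sizes, no filter, a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, robust dispersion, a replicate block, camera with an estimated correlation, fry, and leaving out each library in turn. Thinning of all libraries to the depth of the shallowest was added after the data were seen. When a quiescent McSC library is left out, the remaining one is assumed to vary like the melanocyte libraries. Replicates of a group differed by more than sampling noise (chi-square per gene from 43.8 to 164), so none was treated as a repeat of another library.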

Results

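Gene expression was compared between quiescent McSC, the unpigmented reserve cells of the hair follicle's pigment lineage, and melanocytes of growing follicles. The series title places the data in a study of BMP signaling between activated McSC and differentiation. Both populations were sorted by a green reporter driven by the melanoblast gene Dct, medium to low integrin α6, and absence of CD31, CD45, CD140a, Sca1 and CD34. The melanocytes were also sorted for a Lef1 reporter and for c-Kit. Total counts were 67483295 and 124530834 in quiescent McSC replicates 1 and 2, and 36502516, 67275054 and 17512381 in melanocyte replicates 1 to 3. Age, hair cycle stage, reporter strain and gate all differed between the groups together, so no difference below can be assigned to one of them. Hair follicle and fibroblast markers were also higher in the melanocyte libraries (median log2 fold changes 6.96 and 6.07). Higher in melanocytes or in quiescent McSC therefore refers below to the libraries, and does not assign the RNA to a cell type.

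Between the groups, 55.4% of the tested genes were called, a share that fell with the replicate number as a block (7412 of 16953 genes). Under that block melanocyte replicate 3, the only library with its number, has no weight on the group difference. In the main fit, 4937 of 16953 genes tested were higher in melanocytes and 4448 higher in quiescent McSC. Of these, 3436 and 2833 differed at least 2-fold. In 9367 of the 9385 called genes (99.8%) the groups did not overlap, against 74.5% of all tested genes and 20% by chance for 2 against 3 libraries. Of the calls, 52.6% were higher in melanocytes, and 63.7% with library size as the only scaling, which moved the median log2 fold change of all genes from 0.03 to 0.26. Without quiescent McSC replicate 2 the number of genes higher in quiescent McSC was 2955.

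The genes used for sorting differed in both directions. Lef1, a transcription factor of the WNT pathway (chromosome 3, 131110297 to 131224357), was higher in melanocytes, at 264.5 ± 13.3 against 16.3 ± 4.30 CPM (log2 fold change 4.02 ± 0.21 SE, adjusted p = 7.33e-05). Kit, the receptor of stem cell factor (chromosome 5, 75574987 to 75656722), was higher in quiescent McSC, at 1599 ± 82.1 against 365 ± 181 CPM (-2.13 ± 0.46, adjusted p = 0.00923). Dct, an enzyme of melanin synthesis (chromosome 14, 118012790 to 118052246), stood at 10990 ± 766.5 CPM in quiescent McSC and 4452 ± 2949 CPM in melanocytes and was not called (adjusted p = 0.155). Its melanocyte libraries read 1073, 5777 and 6505 CPM. Without melanocyte replicate 1, Dct was called higher in quiescent McSC (log2 fold change -0.83, adjusted p = 0.0081). Genes of the depleted surface markers were higher in melanocytes at low levels: Pdgfra (CD140a) at 38.8 ± 31.6 against 0.537 ± 0.443 CPM, Cd34 at 21.3 ± 7.32 against 2.13 ± 1.18 CPM, Pecam1 (CD31) at 10.1 ± 4.79 against 0.443 ± 0.0813 CPM, and Ptprc (CD45) at 1.87 ± 0.950 against 0.171 ± 0.0608 CPM. Ly6a (Sca1) and Itga6 were also called higher in melanocytes. The call of Ly6a was lost without quiescent McSC replicate 1 (adjusted p = 0.151) or melanocyte replicate 2 (0.0638), and that of Itga6 without the same libraries (0.121 and 0.0513). With the replicate number as a block the call of Ly6a was also lost (0.054).

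The largest differences toward melanocytes were genes of the hair shaft and its sheaths. Krt34, a hair keratin, had no count in quiescent McSC and was at least 1536-fold higher in melanocytes. Krtap7-1, a keratin-associated protein, had 1 count in quiescent McSC against 14650 in melanocytes (ratio 20040, interval 3596 to 791600). Krt83 had 2 counts (ratio 10090, interval 2792 to 83320), Krt72 3 counts (4535, 1551 to 22000) and Gprc5d 3 counts (2809, 960.9 to 13630). Krt33a (log2 fold change 11.62 ± 0.89), Krtap15 (10.88 ± 1.19) and Krtap11-1 (10.58 ± 0.94) completed the 8 largest. Toward quiescent McSC, Scn10a, a sodium channel gene (chromosome 9, 119608456 to 119719322), had no count in melanocytes and was at least 875.7-fold higher. The complement gene C4b reached 1224 ± 325 against 4.12 ± 0.855 CPM. The interferon-induced GTPase genes Tgtp1 (-10.02 ± 0.79) and Tgtp2 (-8.87 ± 0.65) and the MHC class I gene H2-Q8 (-9.13 ± 0.59) are near-identical to relatives, so their split is uncertain. Nppb (-8.42 ± 0.61), Slc6a7 (-8.21 ± 0.86) and Clvs1 (-8.13 ± 0.44) were the others.

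Markers of other skin cell types were mostly higher in the melanocyte libraries. Of 17 hair follicle and hair shaft markers, 15 were higher in melanocytes and 1, Krt79, was lower (median log2 fold change 6.96, adjusted p = 2.44e-05), and Tchh reached 1580 ± 575 against 2.54 ± 0.444 CPM. Of 14 fibroblast and dermal papilla markers, 13 were higher (6.07, adjusted p = 2.44e-05), 14 adjusted over the list alone, with Col1a1 at 540 ± 395 against 3.13 ± 1.17 CPM and Corin at 175 ± 237 against 0.359 ± 0.218 CPM. Melanocyte replicates 1 to 3 read 996, 322 and 302 CPM for Col1a1 and 449, 45.9 and 31.1 CPM for Corin. All 11 muscle and pericyte markers were higher (6.10, or 5.98 with genes absent from a group at their bound, adjusted p = 1.56e-05). So were 9 of 10 endothelial (4.25, adjusted p = 0.000752; Esam was lower), 9 of 15 immune (3.41, adjusted p = 0.0111; Cd207 was lower) and 6 of 8 erythroid and adipocyte markers (4.05, adjusted p = 0.00979). Unless stated, counts adjusted over the list alone were the same. None of these 6 calls held with an estimated correlation (adjusted p = 0.391 for each), a setting under which 0 of the 23 gene lists passed either. Keratinocyte markers divided into 7 higher and 6 lower of 14 (adjusted p = 0.792). Trp63, Dsp, Krt5 and Sfn were among those higher in melanocytes. Krt10 (-4.56 ± 0.68, at 959 ± 427 CPM), Krt1 and Krtdap were among those higher in quiescent McSC. No split between basal and differentiation genes was tested. The median (0.02) and mean (-0.72) of the keratinocyte list differed in sign. Its median was -0.12 without quiescent McSC replicate 1 and -0.14 without melanocyte replicate 1. Of 10 Schwann cell markers, 3 were higher, including Mbp and Cldn19, and 3 lower, including Pmp22 and Egr2, and 4 and 3 adjusted over the list alone (adjusted p = 0.792). Krt79 lost its call without quiescent McSC replicate 1 or 2, or melanocyte replicate 2 or 3 (0 markers lower in each). With library size only it was lost too (0 lower). Esam lost its call without quiescent McSC replicate 2 (0 lower), and 1 Schwann marker was higher without melanocyte replicate 2. The call of Cd207 was not kept after thinning, where 0 of the 10 immune markers still tested were lower in melanocytes.

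**Figure D1:**
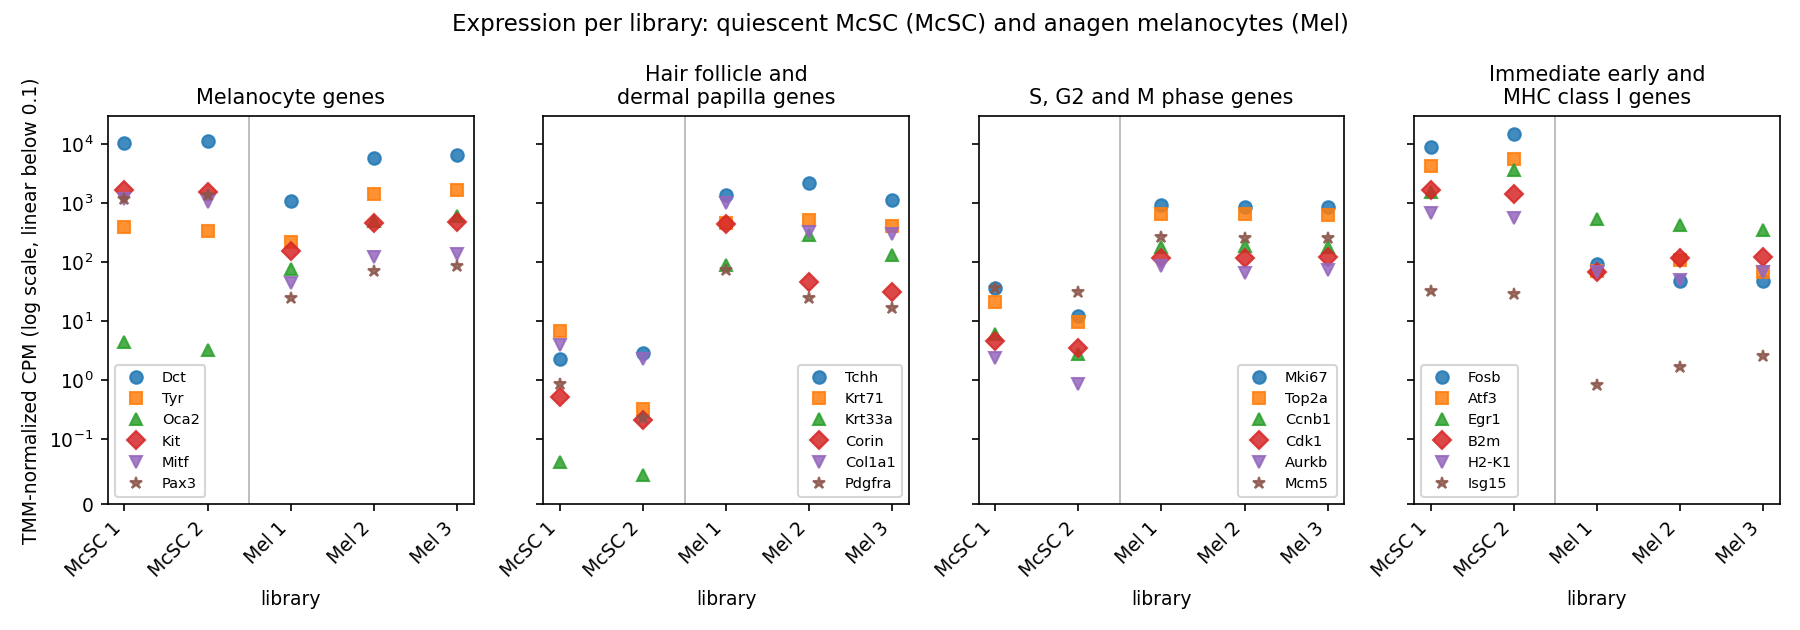
TMM-normalized CPM of 24 genes in each of the 5 libraries (McSC, quiescent melanocyte stem cells; Mel, melanocytes) on a log axis that is linear below 0.1; each symbol is 1 gene in 1 library. Mki67 read 919, 874 and 873 CPM in the melanocyte libraries, whereas Dct read 1073, 5777 and 6505 CPM.

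Pigment genes were higher in melanocytes for a subset of the list. Of 18 genes of melanin synthesis and melanosome proteins, 5 were higher in melanocytes, 0 were lower and 13 were not called, and 4 were higher adjusted over the list alone (median log2 fold change 1.59, camera adjusted p = 0.271). The 5 were Oca2, the melanosomal pH regulator (394 ± 281 against 3.83 ± 0.845 CPM), Slc24a4 (5.93 ± 0.88), Mreg (2.58 ± 0.24), Trpm1 (2.40 ± 0.73) and the cystine transporter Slc7a11 (2.26 ± 0.30). Tyrosinase (Tyr) stood at 1117 ± 785 against 367 ± 46.4 CPM (adjusted p = 0.134). In 13 of the 18 genes melanocyte replicate 1 stood at a log2 ratio of -1 or lower to replicate 3 (median -2.57), whereas the median ratio of fibroblast markers was 1.55. Without it, 12 genes were higher and 2 lower (adjusted p = 0.00474), and without melanocyte replicate 2, 4 were higher and 1 lower.

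Genes of melanocyte identity were in part higher in quiescent McSC. Of 20 lineage regulators, 9 were higher in quiescent McSC, 3 higher in melanocytes and 8 not called, the same adjusted over the list alone (median -1.01, adjusted p = 0.0835; 0.0395 without melanocyte replicate 3). Pax3 (1289 ± 141 against 60.7 ± 32.1 CPM; -4.41 ± 0.52), Mitf, the master regulator of melanocytes (-3.45 ± 0.47), Zeb1 (-3.54 ± 0.18) and Zeb2 (-2.54 ± 0.13) were higher in quiescent McSC. Lef1, the melanocortin receptor gene Mc1r (4.04 ± 0.80) and Snai2 (0.85 ± 0.16) were higher in melanocytes. Only the melanocytes were sorted for a Lef1 reporter, so the gate itself may give the difference in Lef1. Hair follicle (median 6.96) and fibroblast markers (6.07) were higher in the same melanocyte libraries. Melanocyte replicate 1 stood at a log2 ratio of -1 or lower to replicate 3 in 9 of the 20 regulators, including Sox10 (-1.96), Pax3 (-1.80) and Mitf (-1.67). Of 20 genes of melanosome transport and biogenesis, 10 were higher in quiescent McSC, among them Sytl2 (-2.89 ± 0.27), Lyst (-1.66 ± 0.20) and Ap3d1 (-0.78 ± 0.13), and 3 in melanocytes (Rab38, Rab32, Bloc1s3), the same adjusted over the list alone (adjusted p = 0.226). The latter counts were 4 and 1 without either quiescent McSC library, and 6 and 3 without melanocyte replicate 2, and with library size only they were 7 and 6. Of 18 neural crest and glial genes, 8 were higher in quiescent McSC, including Erbb3 (-1.75 ± 0.11), and 5 in melanocytes, including Ngfr, Mbp, Gap43 and Gfra3, or 8 and 7 adjusted over the list alone (adjusted p = 0.621; median and mean differed in sign); the 5 became 3 without quiescent McSC replicate 1.

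BMP pathway genes outside the cell and at its surface moved in both directions. Of 25 genes for BMP ligands, receptors and extracellular regulators, 12 were higher in melanocytes, 4 in quiescent McSC (Eng, Acvrl1, Acvr2a, Twsg1) and 9 not called, or 13 and 5 adjusted over the list alone (median 1.23, adjusted p = 0.226). Bmp7 (105 ± 10.9 against 17.8 ± 4.34 CPM; 2.57 ± 0.20, adjusted p = 0.000216) and Bmp2 (2.65 ± 0.31) were higher in melanocytes, and Eng, a co-receptor, was higher in quiescent McSC (-2.50 ± 0.23). In the same libraries the fibroblast and dermal papilla markers had a median of 6.07. The counts were 7 and 2 without quiescent McSC replicate 1 and 6 and 3 without replicate 2, and the median was 0.46 without melanocyte replicate 1. The type I receptor Bmpr1a (chromosome 14, 34411061 to 34503336) stood at 198 ± 28.3 CPM in melanocytes and 157 ± 11.15 CPM in quiescent McSC (0.34 ± 0.15, adjusted p = 0.101) and was called with library size only (0.014). Bmpr2 (0.42 ± 0.13) and Acvr1 (0.47 ± 0.13) were called higher in melanocytes, and both calls were lost without either quiescent McSC library or melanocyte replicate 2 (adjusted p = 0.067, 0.202 and 0.0777 for Bmpr2, and 0.08, 0.131 and 0.0746 for Acvr1); that of Bmpr2 was also lost without melanocyte replicate 3 (0.0678), and both with the replicate number as a block (0.151 and 0.0568). Bmpr1b had 5 counts in quiescent McSC and 58 in melanocytes (3.79 ± 0.88), a call lost without quiescent McSC replicate 1 (0.0821) or 2 (0.0666).

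BMP target genes moved in both directions. Of 18 SMAD and target genes, 8 were higher in melanocytes, 7 in quiescent McSC and 3 not called, or 9 and 7 adjusted over the list alone (median 0.21, adjusted p = 0.621). The median was 0.07 without melanocyte replicate 2 and 0.43 with library size only. Msx2 (218 ± 18.15 against 4.39 ± 1.87 CPM), Msx1 (6.64 ± 0.61) and the inhibitory SMAD gene Smad7 (1.67 ± 0.15) were higher in melanocytes; Msx genes are also expressed by hair follicle epithelium, whose markers had a median of 6.96. Id1, a direct BMP target (chromosome 2, 152736251 to 152737410), was higher in melanocytes (136 ± 27.4 against 66.5 ± 1.32 CPM; 1.03 ± 0.18, adjusted p = 0.00414). Id3 (-0.86 ± 0.24, adjusted p = 0.025) and Id4 (-0.91 ± 0.21, adjusted p = 0.011) were higher in quiescent McSC, and Id2 was not called (0.84 ± 0.33, adjusted p = 0.0698). Id2 was called higher in melanocytes without melanocyte replicate 1 (0.00035) and by DESeq2 or library size only (0.0331 and 0.0277). The call of Id3 was lost without quiescent McSC replicate 2 (0.162), without melanocyte replicate 3 (0.0586) and with library size only (0.0505), and that of Id4 without quiescent McSC replicate 2 (0.0789), where 7 targets were higher in melanocytes and 1 in quiescent McSC.

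**Figure D2:**
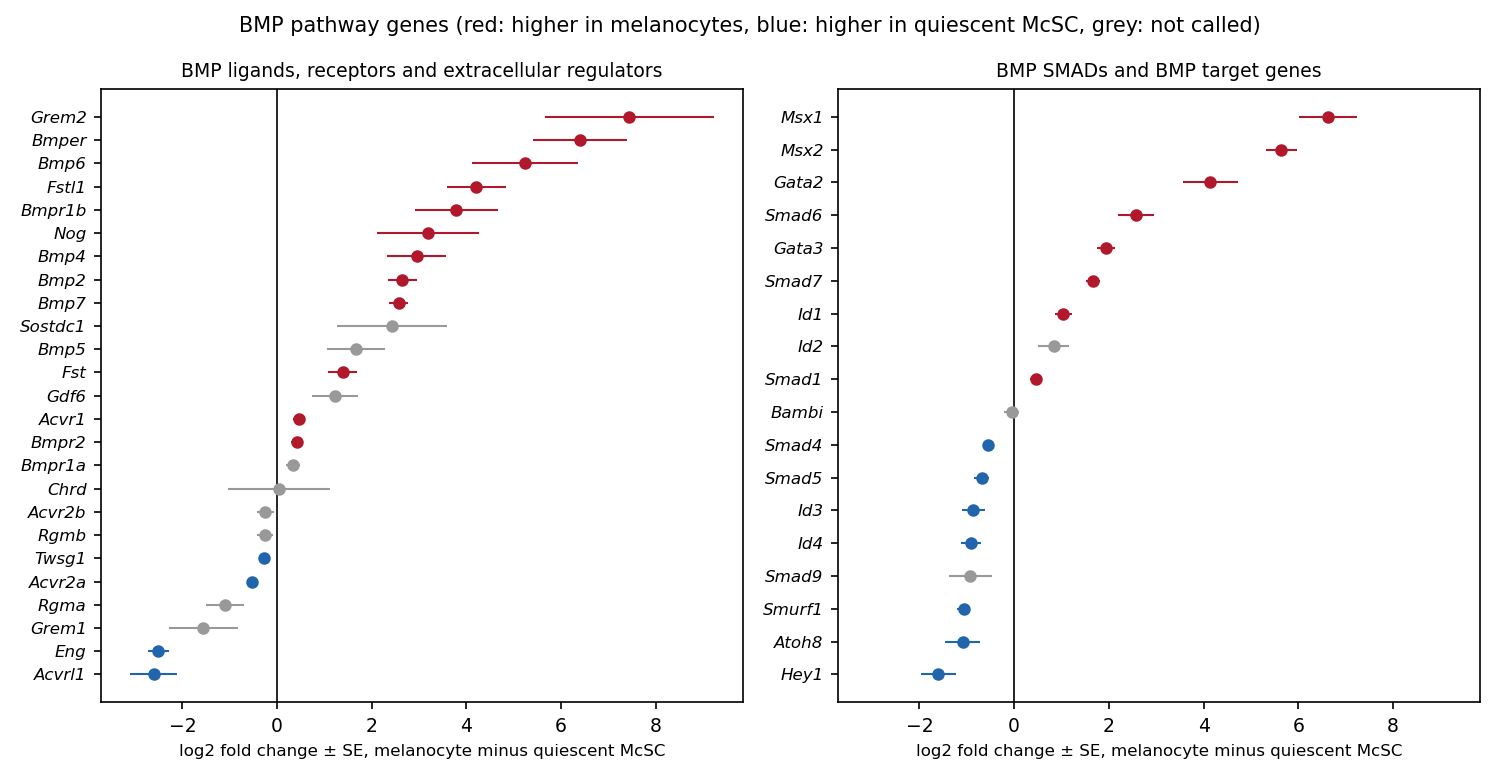
Log2 fold change (melanocyte minus quiescent McSC) of the BMP pathway genes with SE bars from the edgeR fit; red, higher in melanocytes; blue, higher in quiescent McSC; grey, not called. Msx1 and Msx2 lie at 6.64 and 5.64, whereas Id3 and Id4 lie at -0.86 and -0.91.

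Cell cycle genes were almost uniformly higher in melanocytes. Of 34 genes of S, G2 and M phase, 31 were higher in melanocytes, 0 lower and 3 not called (Mcm4, Pcna, Gins2), the same adjusted over the list alone (median 4.10, adjusted p = 1.45e-12; adjusted p = 0.579 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, stood at 119 ± 1.65 against 4.08 ± 0.791 CPM, Plk1 at 71.0 ± 4.65 against 3.18 ± 0.261 CPM, and Mki67 at 888 ± 26.4 against 24.4 ± 17.25 CPM. Hair follicle markers moved with these genes (median 6.96). Of 21 cell cycle inhibitors and quiescence genes, 13 were higher in quiescent McSC and 5 in melanocytes (Rbl1, E2f4, Cdkn2b, Cdkn2c, and Cdkn2a with 1 count in quiescent McSC and 23 in melanocytes, ratio 31.46, interval 5.109 to 1296), or 14 and 5 adjusted over the list alone (median -1.09, adjusted p = 0.0349; adjusted p = 0.579 with an estimated correlation). The member Btg2 is also in the immediate early list, all 25 members of which were higher in quiescent McSC (median -2.59). A response to the preparation of the cells cannot be told apart for this list either. The pocket protein gene Rbl2 (-2.46 ± 0.11), Klf4 (-4.16 ± 0.22) and Cdkn1a (577 ± 104.5 against 138 ± 22.9 CPM) were higher in quiescent McSC, and Rbl1 (3.04 ± 0.10) in melanocytes. Without quiescent McSC replicate 2 the counts were 12 and 3.

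Immediate early and interferon-response genes were higher in quiescent McSC. All 25 immediate early and dissociation stress genes were higher there, the same adjusted over the list alone (median -2.59, adjusted p = 8.97e-10; adjusted p = 0.579 with an estimated correlation). Fosb reached 12150 ± 4420 against 62.7 ± 25.1 CPM, Atf3 4969 ± 917 against 82.8 ± 23.7 CPM, and Klf6 and Dnajb1 differed by -4.14 ± 0.25 and -2.60 ± 0.14. Of 24 genes of interferon response and antigen presentation, 21 were higher in quiescent McSC, 0 lower and 3 not called (Cd74, H2-Ab1, Ifitm3), the same adjusted over the list alone (median -2.91, adjusted p = 1.49e-08; adjusted p = 0.579 with an estimated correlation). H2-D1, an MHC class I gene, stood at 1407 ± 164 against 123.6 ± 17.3 CPM, and Stat2 and Tap1 differed by -3.02 ± 0.13 and -2.96 ± 0.12. The keratinocyte markers Krt10 (959 against 40.6 CPM), Krt1 (262 against 12.7 CPM) and Krtdap (148 against 4.59 CPM) were also higher in quiescent McSC, as was Krt79 (112.5 against 25.7 CPM). The keratinocyte list as a whole divided into 7 genes higher in melanocytes, Krt5, Trp63, Dsp and Sfn among them, and 6 higher in quiescent McSC. Of 15 immune cell markers, 9 were higher in melanocytes (median 3.41) and 1, Cd207, was higher in quiescent McSC, a call not kept after thinning.

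Among signaling lists, 14 of 24 WNT targets and regulators were higher in melanocytes, including Znrf3 (1.90 ± 0.10), and 3 in quiescent McSC (Myc, Dkk3, Tcf7l2), the same adjusted over the list alone. Lef1, whose reporter gated the melanocytes only, is a member of this list. The list test missed the threshold (median 1.03, adjusted p = 0.0597; 0.03 and 0.0487 without quiescent McSC replicates 1 and 2, and 0.0395 without melanocyte replicate 3). Of 18 Notch pathway genes, 9 were higher in melanocytes, among them the ligand genes Jag2 (3.54 ± 0.16) and Dll1 (2.74 ± 0.22), and 4 in quiescent McSC (Notch2, Hey1, Hey2, Maml1; adjusted p = 0.226). Hair follicle markers, with a median of 6.96, moved with both lists. Of 20 TGF-beta genes, 5 were higher in quiescent McSC (including Tsc22d1, Ski, Skil and Tgfbr3) and 2 in melanocytes (Tgfb1, Inhba), or 4 and 1 adjusted over the list alone (adjusted p = 0.226); these counts were 4 and 1 without either quiescent McSC library and 10 and 3 without melanocyte replicate 1, and 4 and 4 with library size only. Receptor tyrosine kinase and MAPK feedback genes gave 7 higher in melanocytes, including Ccnd1 (3.57 ± 0.25) and Etv4 (2.45 ± 0.14), and 6 higher in quiescent McSC, including Dusp5 (-4.39 ± 0.18), of 18 (adjusted p = 0.899). The Notch and MAPK counts were the same adjusted over the list alone.

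Oxidative phosphorylation genes were slightly higher in melanocytes. Of 39, 22 were higher and 1, the regulator Ppargc1a (-2.38 ± 0.25), was lower, or 24 and 1 adjusted over the list alone (median 0.48, adjusted p = 0.0094; adjusted p = 0.856 with an estimated correlation and 0.0598 under fry). Hair follicle (6.96) and fibroblast markers (6.07) were higher in the same libraries. Cox5a (107 ± 17.4 against 39.3 ± 3.56 CPM) and Ndufa4 (1.05 ± 0.15) were examples. The 22 fell to 7 and 5 without quiescent McSC replicates 1 and 2. Of 21 glycolysis genes, 11 were higher, including Pgam1 (1.88 ± 0.16) and Pdk1 (1.52 ± 0.11), and 5 lower (Hk1, Pfkp, Eno2, Slc2a1, Slc2a3), or 11 and 6 adjusted over the list alone (adjusted p = 0.214). Of 32 extracellular matrix, basement membrane and integrin genes, 17 were higher in melanocytes, including Sparc (588 ± 50.4 against 30.0 ± 5.18 CPM), Itga3 and Lama5, and 6 lower, the same adjusted over the list alone (adjusted p = 0.103; 0.0328 without melanocyte replicate 3); fibroblast markers moved with them (median 6.07).

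The remaining lists were not called. Of 31 lysosome and autophagy genes, 9 were higher in quiescent McSC, including Map1lc3b (-1.43 ± 0.13), Sqstm1 and Gabarapl1, and 1 in melanocytes (Gusb), or 8 and 1 adjusted over the list alone (adjusted p = 0.107; 0.0395 without melanocyte replicate 3); without quiescent McSC replicate 1, replicate 2 and melanocyte replicate 1 in turn, 6, 4 and 11 were higher in quiescent McSC and 0, 0 and 4 in melanocytes, and with library size only 7 and 3. Unfolded protein response genes gave 8 higher in quiescent McSC, including Atf4 (-2.11 ± 0.13), Ddit3 and Herpud1, and 7 in melanocytes of 20, or 9 and 8 adjusted over the list alone (adjusted p = 0.546); 6 and 4, and 7 and 4, were called without quiescent McSC replicates 1 and 2. Of 19 clock genes, 8 were higher in quiescent McSC, including Nfil3 (-3.21 ± 0.15), Clock and Arntl, and 4 in melanocytes (Per2, Per3, Cry1, Hlf), the same adjusted over the list alone (adjusted p = 0.261; median and mean differed in sign), the 4 becoming 2 without quiescent McSC replicate 2. Cholesterol synthesis had 9 of 19 higher in melanocytes, including Mvd and Fdps, and 2 lower (including Msmo1; adjusted p = 0.261), and oxidative stress defence 9 of 20 higher, including Gsr and Gclc, and 6 lower, including Nfe2l2 (-1.98 ± 0.13; adjusted p = 0.691), both the same adjusted over the list alone. Without quiescent McSC replicates 1 and 2, the genes higher were 6 and 5 for cholesterol synthesis, with 1 lower in each, and 5 and 5 for stress defence; without melanocyte replicate 3, 8 cholesterol genes were higher and 1 lower, and with library size only 11 and 1. Of 45 ribosomal protein genes, 42 were not called, Rpl27 and Rplp2 were higher and Rpl37 lower in melanocytes, and 0 were called adjusted over the list alone (adjusted p = 0.784; median and mean differed in sign). No ribosomal gene was called without quiescent McSC replicate 1 or 2 (0 in each), 1 was higher and 4 lower without melanocyte replicate 2, and 1 higher and 0 lower without replicate 3. With library size only, 6 were higher and 0 lower. The calls of Rpl37 and Rplp2 were also lost with the replicate number as a block (0.154 and 0.156).

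**Figure D3:**
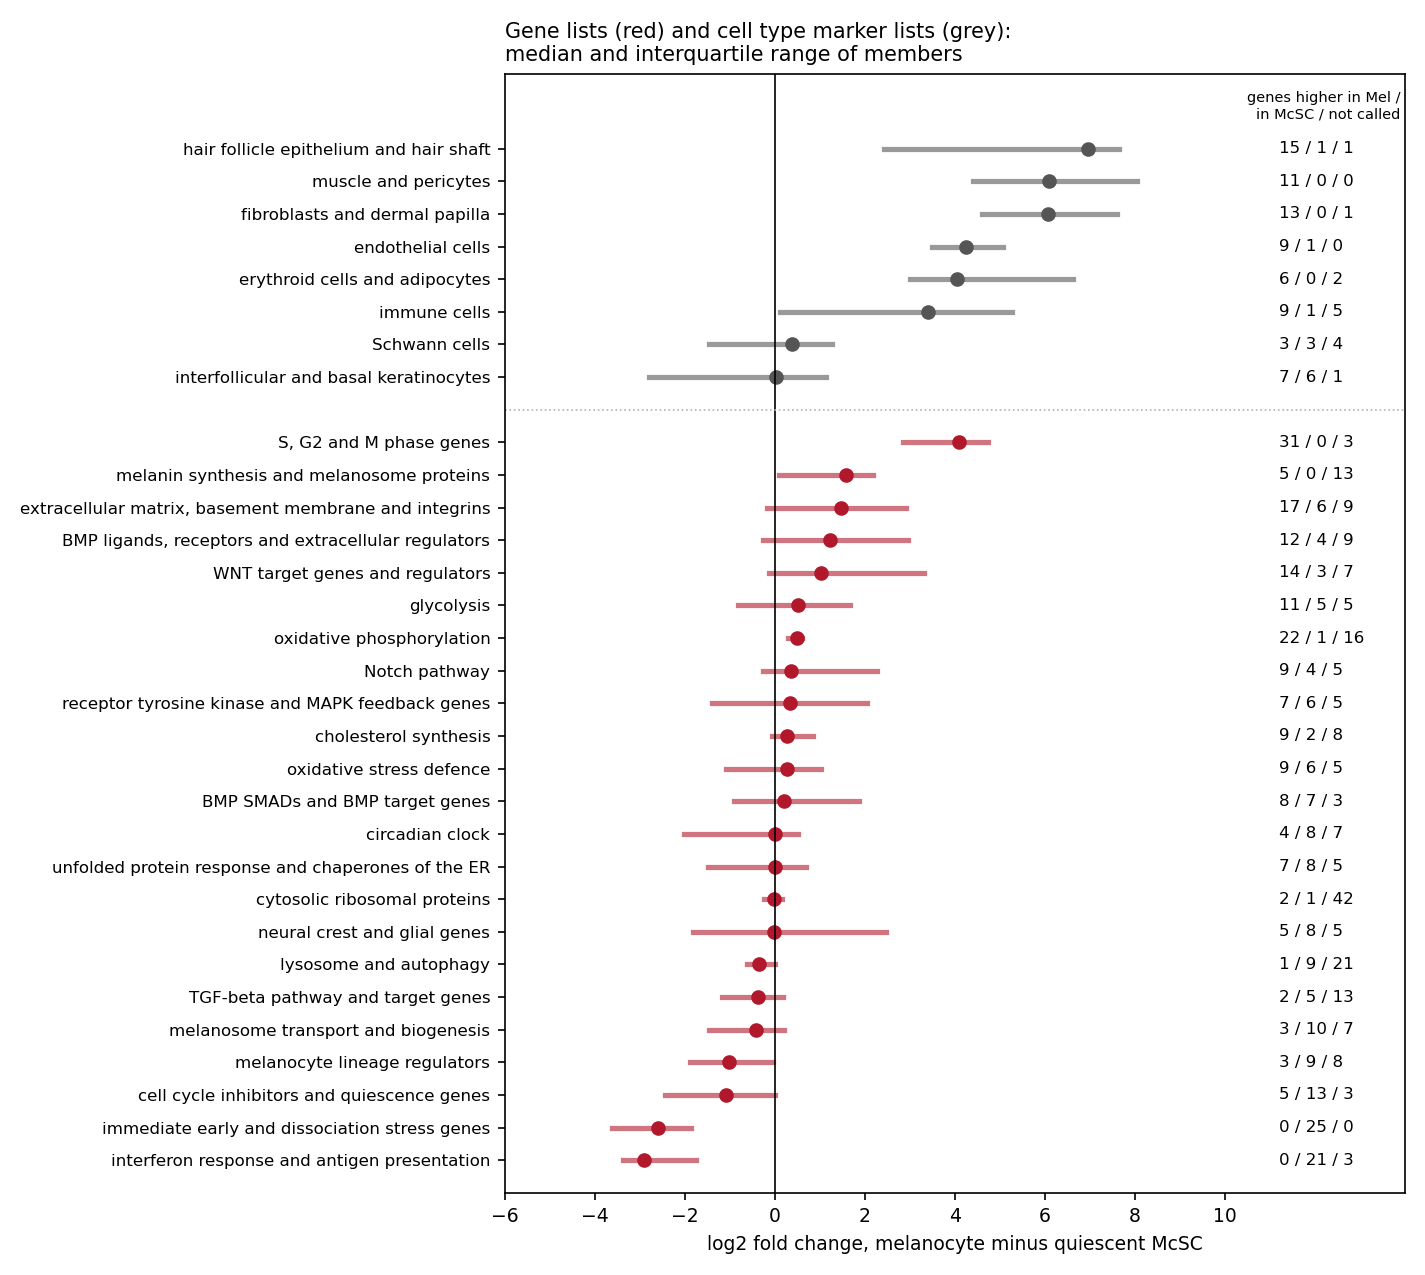
Median (point) and interquartile range (bar) of the members' log2 fold change, melanocyte minus quiescent McSC, for the 23 gene lists (red) and 8 marker lists (grey), with the numbers of members higher in melanocytes, higher in quiescent McSC and not called. Medians run from -2.91 for the interferon list to 6.96 for hair follicle markers.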

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

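Thinning was chosen after the data were seen, the other settings before. No called gene was called in the opposite direction in any of the 15 refits. Without quiescent McSC replicate 2, 2955 genes were higher in quiescent McSC, the lowest of a leave-one-out range of 2955 to 4857, and the stricter filter, which tests fewer genes (11866), left 2215 genes at least 2-fold higher in melanocytes. Thinning gave 8689 calls, and the WNT list passed (0.0323). The melanin list ranged from 0.00474 to 0.454 in adjusted p over the left-out libraries, and passed only without melanocyte replicate 1. The lineage list passed under fry (0.0275), library size only (0.0414) and without melanocyte replicate 3 (range 0.0395 to 0.122), and the BMP target list under fry (0.00507), which tests a list without comparing it with other genes. Under fry the WNT (0.00321), Notch (0.00723), glycolysis (0.0275), clock (0.000981) and keratinocyte lists (0.0355) passed too, and oxidative phosphorylation did not (0.0598; range over all alternatives 0.000942 to 0.856). The cell cycle and the inhibitor lists both stood at 0.579 with an estimated correlation. No list passed with that setting, 0 of 23 gene lists and 0 of 8 marker lists, so a lost call does not set a list apart. The WNT list went from 0.0597 to 0.579 there, although its estimated correlation (0.0172) was near the preset 0.01. That setting also takes its degrees of freedom from the few libraries, so a call lost there does not show correlation between the genes of a list. The cause of the other differences between settings was not tested.

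With the replicate number as a block, 7412 genes were called, and 7180 of the 9385 calls were kept. The lineage (0.0255), WNT (0.0483), lysosome (0.032) and extracellular matrix lists (0.0205) passed. Melanocyte replicate 3 is the only library with its number, so under the block it adds nothing to the group difference. The same lists passed camera without that library (adjusted p = 0.0395, 0.0395, 0.0395 and 0.0328). The block is therefore no separate check, and the fall in calls cannot be read as an effect of pairing. Among the 123 genes of the naming rule, the calls lost were Bmpr2 (0.151), Acvr1 (0.0568), Ly6a (0.054), Rpl37 (0.154) and Rplp2 (0.156). Nothing in the labels says that equal numbers share an animal or day, so the numbers were not taken to pair the samples. Deviations of same-numbered libraries from their group means correlated at 0.0404 and -0.0552 across genes. With 2 quiescent McSC libraries the deviations of 1 mirror those of the other (correlation -1). These values are therefore not independent and decide nothing on pairing.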

Other observations

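All tests in this part, thinning included, were chosen after the data were seen; only the bounds for library depth were written before thinning was run. Genes were grouped by the shared stem of their symbols, giving 216 families with at least 10 tested members, of which 22 passed camera at the preset correlation; no estimated correlation was run for them. Beyond the hair keratins, 38 of 40 keratin-associated protein genes (Krtap) were higher in melanocytes (median log2 fold change 7.84, adjusted p = 6.15e-09). Of 10 Hoxb genes, 9 were higher (2.97, adjusted p = 0.00957), and of 17 Wnt ligand genes 12 were higher and 2 lower, Wnt7a and Wnt16 (3.67, adjusted p = 0.00994). Of 11 Bmp genes, 9 were higher and 1, Bmp15, was lower (2.57, adjusted p = 0.046). Hair follicle (median 6.96) and fibroblast markers (6.07) were higher in the same libraries. Mitochondrial ribosomal protein genes rose by a small amount, with 33 of 49 Mrpl (0.51, adjusted p = 0.000519) and 20 of 29 Mrps genes higher (0.46, adjusted p = 0.00957). So did 11 of 14 Psmd genes of the proteasome cap (0.74, adjusted p = 0.00994).

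Toward quiescent McSC, 8 of 11 interferon-induced Gbp genes were higher (median -3.23, adjusted p = 0.00957), as were 11 of 15 Klf transcription factor genes (-1.72, adjusted p = 0.00957), 9 of 12 Parp genes (-1.91, adjusted p = 0.00994), 11 of 15 Serpina genes (-4.44, adjusted p = 0.0126) and 9 of 11 Skint genes (-3.68, adjusted p = 0.0142). The keratinocyte markers Krt10 (959 against 40.6 CPM), Krt1 (262 against 12.7 CPM) and Krtdap (148 against 4.59 CPM) moved with these families. The keratinocyte list as a whole divided into 7 genes higher in melanocytes and 6 higher in quiescent McSC. The other families past the threshold were Krt, Myh, Mcm, Exosc and Rad toward melanocytes, and Cyp, Anxa, Pcdhga, Pcdhb and Zscan toward quiescent McSC. Near-identical members of the Gbp, Serpina, Skint and Krtap families can share reads. None of the medians given here changed sign with library size only or with other size factors.

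Melanocyte replicate 1 held less RNA of many melanocyte genes than replicate 3. The first test used the 9 lineage regulators called higher in quiescent McSC, a set taken from these same data. Their median log2 ratio was -0.532 with an upper quartile of -0.453. This lay between the values set for a lower share of melanocytes and for weaker pigmentation, so the test cannot tell these apart. The set did not move together. Of the 9, 4 stood at -1 or lower, including Pax3 (-1.80), Mitf (-1.67) and Kit (-1.62), whereas Zeb1 stood at -0.532 and Zeb2 at 0.26. Its median is therefore a poor measure of melanocyte share. A second look, taken because that test was undecided, found 9 of all 20 lineage regulators at a ratio of -1 or lower, against 6.11% of all genes; bounds for it were set with the count already known and were withdrawn, so it decides nothing. A loss of melanocytes with the other cells in unchanged proportion is argued against, since the fibroblast marker median exceeded the hair follicle one by 1.27 and their interquartile ranges did not overlap. More dermal cells in that library were not tested as an explanation. The sort excluded CD140a, a fibroblast surface marker, yet its gene Pdgfra stood at a log2 ratio of 2.15 (replicate 1 over 3). Of 14 fibroblast markers, 11 stood at a ratio of 1 or more, so the gate alone does not argue against dermal RNA.

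Of the 34 S, G2 and M phase genes, 31 were called higher in melanocytes. Library depth is argued against, since 31 of 34 members were called after thinning. The list's median log2 ratio between melanocyte replicates 1 and 3 was -0.00667 while that of the melanin list was -2.57. Cycling cells of other types may give this. The sort required the Dct reporter and c-Kit, yet hair follicle markers were higher in the melanocyte libraries (median log2 fold change 6.96). Cycling melanocytes as the source of all of the difference cannot be told apart from cycling cells of other types. The ratio (-0.00667) rests on 1 library. Age and hair cycle stage stay open and untested.

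Immediate early and interferon genes were higher in quiescent McSC. Immune cells marked by Ptprc, Tyrobp, Laptm5, Lyz2 and Csf1r are argued against in those libraries. These 5 markers had a median log2 fold change of 4.06, that is higher in melanocytes. Of all 15 immune markers, 9 were higher in melanocytes, 5 not called and 1, Cd207, higher in quiescent McSC. That call was not kept after thinning, where 0 of the 10 immune markers still tested were higher in quiescent McSC. Cells marked by Cd207 were not tested as a source and stay open. Library depth is argued against by 46 of 49 members called after thinning. A response to the preparation of the cells may raise immediate early genes (median -2.59), and cannot be told apart from a state of the cells, because no group was prepared both ways. Keratinocytes were not tested as a source. Krt10 (959 against 40.6 CPM), Krt1 (262 against 12.7 CPM) and Krtdap (148 against 4.59 CPM) were higher in the same libraries. Of all 14 keratinocyte markers, 6 were higher there, whereas 7, Krt5, Trp63, Dsp and Sfn among them, were higher in melanocytes. Age and hair cycle stage stay open too.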
